A study of Mus musculus with 14 samples.

How the data were processed

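Pseudouridylation of ribosomal RNA was measured by Pseudo-seq in spleen RNA of 7 C57BL/6J mice. The labels put 4 animals in a wild-type group and 3 in a group called HET, and the series title and the column names of the deposited table name the genotype as Naf1 heterozygous. Pseudouridine is an isomer of uridine, and in eukaryotic rRNA it is placed mainly by H/ACA small nucleolar ribonucleoproteins. Naf1 (Gene ID 234344) encodes an assembly factor of these particles. In mouse it is a protein-coding gene at chromosome 8, 66859943 to 66890564 in GRCm38, the assembly that mm10 denotes.

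Per the labels' protocols, total RNA was fragmented and derivatised with CMC, a carbodiimide whose adduct stays on pseudouridine after a reversal step. The adduct stops reverse transcriptase, and truncated cDNA was size-selected, circularised, amplified and sequenced on an Illumina instrument. Each animal gave 1 library with 0.4 M CMC and 1 library without it, 14 libraries in all. The submitters' processing notes name the aligner Bowtie, without a version, and the build mm10.

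The deposited table lists 107 positions in rRNA, 39 in 18S, 66 in 28S and 2 in 5.8S, which the series describes as mapped pseudouridines. It gives 1 peak value per animal and position, a score that the authors computed. How the library with CMC and the library without it enter the score is not given in the sources used here. The formula, the window and any scaling between libraries are not given either, so the score has no stated unit, and it is not a percentage of modified molecules. Percentages and ratios given here are of the score, whose 0 is set by that formula, and not of the modification. Values ran from -11.1 to 28.2, and 66 of 749 were below 0. Read depth behind each value is unknown, so no counting interval is given, and the 4 and 3 animals set the precision. Positions are printed as deposited, counted within each rRNA, and the origin of the count is not stated. The deposited means, standard deviations and ratios of the genotypes equal those computed from the animals' columns to within floating-point error. The authors' pass mark was given to 82 positions. Its rule is not stated, but all 82 had a mean over the 7 animals of at least 1.68 and the other 25 had at most 1.28.

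The value columns carry a genotype and a letter (A to D for wild type, E to G for heterozygous), whereas the labels number the animals. Letters were therefore used as names only. The columns of animals, means and standard deviations were mapped to a genotype, and no 2 animals had identical columns.

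Computed here, with the design fixed before the data were examined, were the following. Per site, limma 3.58.1 in R 4.3.3 was fitted to the deposited peak values of all 7 animals (lmFit, eBayes with a mean-variance trend), heterozygous minus wild type, two-sided, with Benjamini-Hochberg adjustment over the 107 sites and a threshold of 0.05. Per animal, the mean peak value over all sites and over each rRNA was compared by exact permutation of the genotype labels over all 35 assignments, two-sided on the absolute difference, so that the smallest possible p is 0.0286. Confidence intervals at 95% for these means come from inverting the exact test. Adjustment was over the 3 rRNA species, over the sites below and above the median of the mean over all animals, and over 12 clusters of at least 3 sites each within 20 nt of the next. The number of sites with a lower heterozygous mean and the similarity of the animals' profiles were tested over the same 35 assignments. The planned test of libraries with CMC against those without could not be run on 1 value per animal. In its place, sites above 0 and at 1 or more in every animal were counted. The level groups and clusters were fixed in advance, but their test and adjustment were chosen after the data were seen. So were the confidence intervals, the bounds per site and the count of sites at which the genotypes' animals do not overlap. Guide RNAs were not used here, and no markers of other cell types apply to rRNA positions.

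Sites named in the text follow a rule fixed before the data were examined. They are those past the adjusted threshold, the 5 with the most positive and the 5 with the most negative moderated statistic, the 5 highest and the 5 lowest by mean over all animals, and every 5.8S site. Exceptions are stated where they occur.

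Alternatives were log2(value + 1) with values below 0 set to 0 first, a minimum mean of 1, scaling by each animal's median, removal of sites within 5 nt of another, removal of each animal in turn, limma without trend, robust limma, weights per animal, an exact test per site, medians over sites, the rotation test fry, Spearman correlation and a detection level of 2. Restriction to sites with the authors' pass mark was added after seeing the data. The per-site fit was tested on simulated data with the real site means and limma's moderated spreads. Of 107 sites, 20 were changed, all with the authors' pass mark. At a peak value left at 50% of wild type the fit recovered 91.6% of the changed sites, with 4.93% of calls false. At 75% it recovered 56.2%, with 5.07% of calls false. Simulated noise was independent between sites, whereas real sites share the animals, so these shares may not carry over to the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the permutation tests and plots.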

Results

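Pseudo-seq peak values were available for 107 rRNA positions in the spleens of 4 wild-type and 3 Naf1 heterozygous mice. The peak value is the authors' score at a position, and how the libraries with and without CMC enter it is not given. The comparison of genotypes addresses whether loss of 1 Naf1 allele alters the extent of rRNA pseudouridylation. P-values of the genotype comparisons rest on the spread between animals, which limma moderates across sites. The read depth of each library is unknown.

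Most listed positions gave a positive peak value in every animal of either genotype. Peak values were above 0 in all 7 animals at 95 of 107 sites, and at 1 or more in all 7 at 81 sites, comprising 29 of 39 in 18S, 50 of 66 in 28S and both in 5.8S. Counted by genotype, 83 sites reached 1 in every wild-type animal and 81 in every heterozygous animal. The sites in the first count only were 28S positions 4204 and 4228, named here after their values were seen. At 28S position 4204 the peak value was 1.99 ± 0.174 (SD, n = 4) in wild type and 1.28 ± 0.355 (SD, n = 3) in heterozygotes. Libraries with and without CMC could not be compared, because 1 peak value is given per animal.

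The strongest signals lay in both large rRNAs and were similar in the genotypes. The highest mean over all animals was at 28S position 1546, with 26.8 ± 1.08 in wild type and 26.0 ± 0.497 in heterozygotes. It was followed by 18S position 823 (26.5 ± 1.10 and 25.1 ± 0.742), 28S position 4013 (25.1 ± 0.754 and 24.9 ± 1.40), 18S position 967 (25.05 ± 1.13 and 23.8 ± 0.781) and 18S position 1005 (23.7 ± 2.31 and 22.9 ± 1.44). All SDs are over 4 wild-type and 3 heterozygous animals. Heterozygous means at these 5 sites were 94.9% to 99.2% of wild type, and none differed by limma, with adjusted p from 0.337 to 0.877. At the other end, 8 sites were below 0 in every animal. The lowest mean was at 28S position 4620, with -9.25 ± 0.696 in wild type and -10.5 ± 0.695 in heterozygotes. Means were also negative at 28S position 3474 (-4.61 ± 2.13 and -0.73 ± 2.91), 28S position 3418 (-1.02 ± 0.226 and -1.22 ± 0.498), 18S position 802 (-0.73 ± 0.136 and -0.88 ± 0.150) and 28S position 1581 (-0.62 ± 0.116 and -0.68 ± 0.111). None of these lowest sites carried the authors' pass mark, and none passed the limma threshold.

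**Figure D1:**
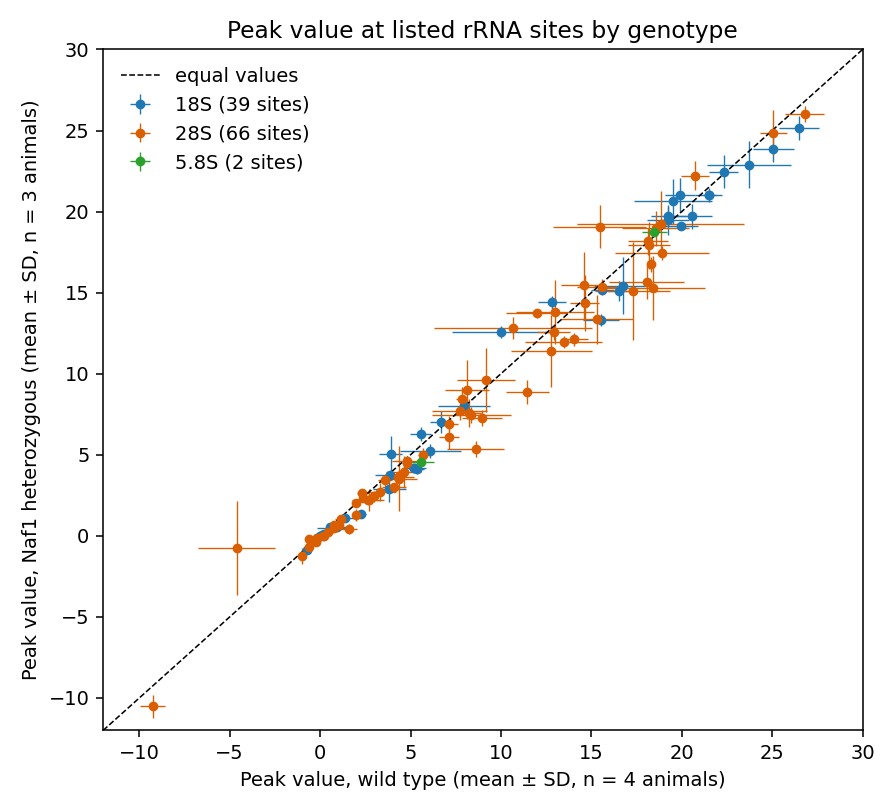
Mean peak value at each of 107 rRNA sites in wild-type mice (horizontal axis, n = 4) against Naf1 heterozygous mice (vertical axis, n = 3), in the authors' score, with SD bars and a dashed line of equal values. Points of 18S, 28S and 5.8S lie near the line from -11 to 27, with Pearson's r of 0.990 across sites.

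The mean peak value over the listed positions was slightly lower in heterozygotes, by an amount within the spread between animals. Over all 107 sites the mean peak value per animal was 9.07 ± 0.291 (SD, n = 4) in wild type and 8.76 ± 0.223 (SD, n = 3) in heterozygotes, 96.6% of wild type. The difference was -0.31 (95% interval -1.26 to 0.36, two-sided exact permutation p = 0.143). As a share of the wild-type mean, the interval runs from -13.9% to 4.0%. On the log2(value + 1) scale, which gives low sites more weight, the mean difference was -0.08 and took the smallest p of the design (exact permutation p = 0.0286). Without wild-type animal A, which had the highest mean (9.48), the difference on the deposited scale was -0.18 (exact permutation p = 0.200, where 3 against 3 animals cannot pass). Scaled by each animal's median it was -0.49 (exact permutation p = 0.343). Each animal's median over sites went the other way, with a difference of 0.12 (exact permutation p = 0.714). That median can fall at a different site in each animal, so its difference is not a typical change per site. It was 6.07 in wild-type animal B, 6.83 to 6.97 in A, C and D, and 6.47 to 7.08 in heterozygotes. Heterozygous means were lower at 75 of the 107 sites.

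In each rRNA the heterozygous mean was slightly below wild type, with overlapping animals. In 18S, the RNA of the small subunit, the mean over 39 sites was 10.4 ± 0.275 (SD, n = 4) in wild type and 10.2 ± 0.184 (SD, n = 3) in heterozygotes, a difference of -0.23 (95% interval -1.15 to 0.33, exact permutation p = 0.286, adjusted p = 0.429). In 28S, the large RNA of the large subunit, the mean over 66 sites was 8.19 ± 0.295 and 7.83 ± 0.259, a difference of -0.36 (95% interval -1.29 to 0.36, exact permutation p = 0.143, adjusted p = 0.429). In 5.8S the mean over 2 sites was 12.02 ± 0.605 and 11.6 ± 0.296, a difference of -0.39 (exact permutation p = 0.514, adjusted p = 0.514). Of the 5.8S sites, position 54 had 5.56 ± 0.752 in wild type and 4.54 ± 0.552 in heterozygotes, and position 68 had 18.5 ± 0.691 and 18.7 ± 0.221, with adjusted p of 0.283 and 0.815 by limma. With 3 rRNA species, at least 2 would need the smallest exact p for any to pass after adjustment. The genotype difference in 18S minus that in 28S was 0.13 (95% interval -0.06 to 0.40, exact permutation p = 0.200), so the subunits were not shown to differ. Without wild-type animal A the differences were -0.10 in 18S, -0.23 in 28S and -0.11 in 5.8S, and without wild-type animal D the 5.8S difference was -0.59. Without heterozygous animal F the 28S difference was also -0.23, and the 18S minus 28S difference was 0.045. Without sites within 5 nt of another the 18S difference was -0.41, and the 18S minus 28S difference turned to -0.020. Scaled by each animal's median, the differences were -0.43 in 18S, -0.52 in 28S and -0.62 in 5.8S. As each animal's median over sites, 18S differed by 0.50, opposite in sign to its mean, and 28S by -0.51 (exact permutation, adjusted p = 0.514 and 0.086). The 18S minus 28S difference was then 1.01 (exact permutation p = 0.086). In 18S, 26 of the 39 sites had a lower heterozygous mean, so 0.50 is not a typical change per site.

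**Figure D2:**
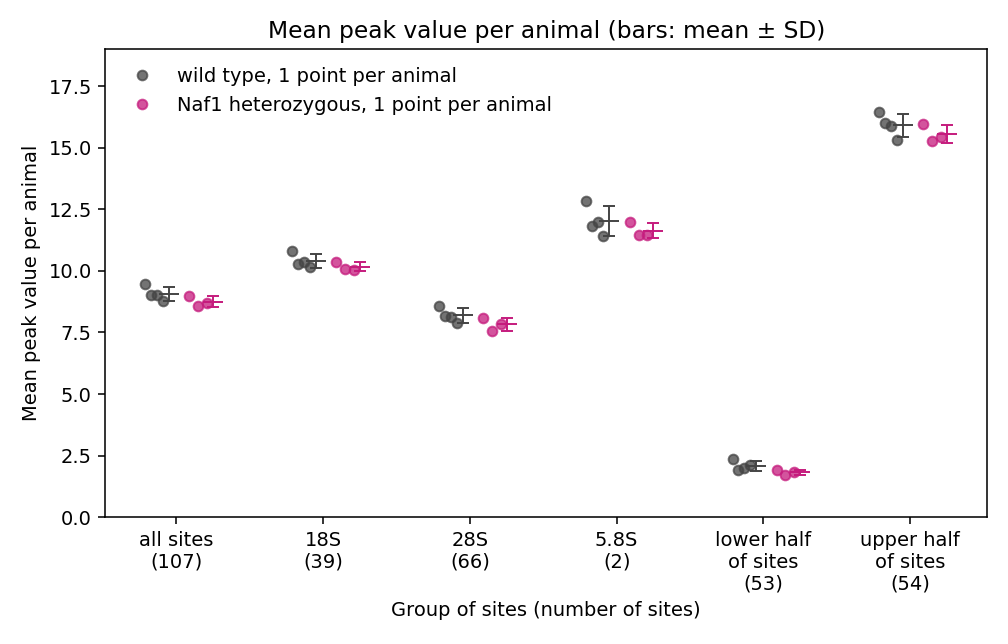
Mean peak value per animal (vertical axis, authors' score) over all sites, each rRNA, and the sites below and above the median level, with 1 point per animal and bars for the mean ± SD of 4 wild-type and 3 heterozygous mice. The genotypes overlap in each rRNA, and over all sites the means are 9.07 and 8.76.

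No site passed the adjusted threshold, although more sites had a lower than a higher heterozygous mean. By limma, 0 of 107 sites had an adjusted p under 0.05, with a smallest adjusted p of 0.125. Adjusted over the list alone, 0 sites passed in 18S, 28S or 5.8S, and the smallest adjusted p by limma was 0.052 in 18S and 0.150 in 28S. An unadjusted p under 0.05 was reached at 20 sites, of which 17 were lower and 3 higher in heterozygotes. The exact permutation test per site gave 9 sites before adjustment, all at the smallest p of the design. After adjustment it could pass only if at least 62 sites shared that p, so its count of 0 carries little weight. Heterozygous means were below wild type at 75 sites and above at 32 (exact permutation p = 0.229). All 3 heterozygous animals lay below all 4 wild-type animals at 15 sites and above them at 2, where chance gives 2.86% or 3.06 sites each way, and 2 of the 35 assignments gave as many as these 17. Without heterozygous animal F, 7 sites reached an unadjusted p under 0.05 by limma in place of 20, against 16 without E and 14 without G. Without animal F the differences at the 20 sites, chosen with that animal included, kept their direction and a median of 94.3% of their size. A rotation test of whether sites move in either direction (fry, mixed) gave an adjusted p of 0.016 over all sites, 0.030 in 18S and 0.015 in 28S. It was run on all 7 animals only, not with an animal left out or on other splits of the animals. The directional form of the same test gave adjusted p of 0.145 for each list by limma's fry.

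Among individual positions, the most negative statistics were at 3 sites in 18S and 2 in 28S. At 18S position 1347 the peak value was 2.25 ± 0.282 (SD, n = 4) in wild type and 1.35 ± 0.044 (SD, n = 3) in heterozygotes. The difference was -0.89 (SE 0.169, 95% interval -1.29 to -0.49, limma adjusted p = 0.125), and the heterozygous mean was 60.3% of wild type. It passed the threshold in 2 alternative fits, with adjusted p of 0.036 when sites within 5 nt of another were removed and 0.035 without wild-type animal D. Over all alternatives its adjusted p by limma ranged from 0.035 to 0.374. At 18S position 34 the values were 5.21 ± 0.351 and 4.21 ± 0.137, 80.9% of wild type, and at 18S position 1175 they were 5.35 ± 0.414 and 4.15 ± 0.344, 77.7% of wild type. At 28S position 4083 they were 8.60 ± 1.57 and 5.37 ± 0.474, 62.4% of wild type. At 28S position 4228, which lacks the authors' pass mark, they were 1.60 ± 0.465 and 0.43 ± 0.286. The last site included an outlying wild-type value of 2.29 in animal A. At all 5 sites every heterozygous animal was below every wild-type animal, and the limma adjusted p was 0.125 for all but 28S position 4083, where it was 0.151.

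The most positive statistics included sites with negative peak values. At 18S position 222 the values were 12.8 ± 0.761 (SD, n = 4) in wild type and 14.4 ± 0.415 (SD, n = 3) in heterozygotes, 112% of wild type, with every heterozygous animal above every wild-type animal. At 28S position 3615 they were 15.5 ± 2.58 and 19.1 ± 1.33, 123% of wild type, and at 28S position 3351 they were 20.7 ± 0.785 and 22.2 ± 0.896, 107% of wild type. The difference at 28S position 3351 was 1.48, and 0.98 without heterozygous animal F. The others were 28S position 3474, given above, and 28S position 4183 (-0.60 ± 0.179 and -0.22 ± 0.194), both negative on average and without the pass mark. The limma adjusted p was 0.216 at 18S position 222 and 28S position 4183 and 0.256 at the other 3.

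**Figure D3:**
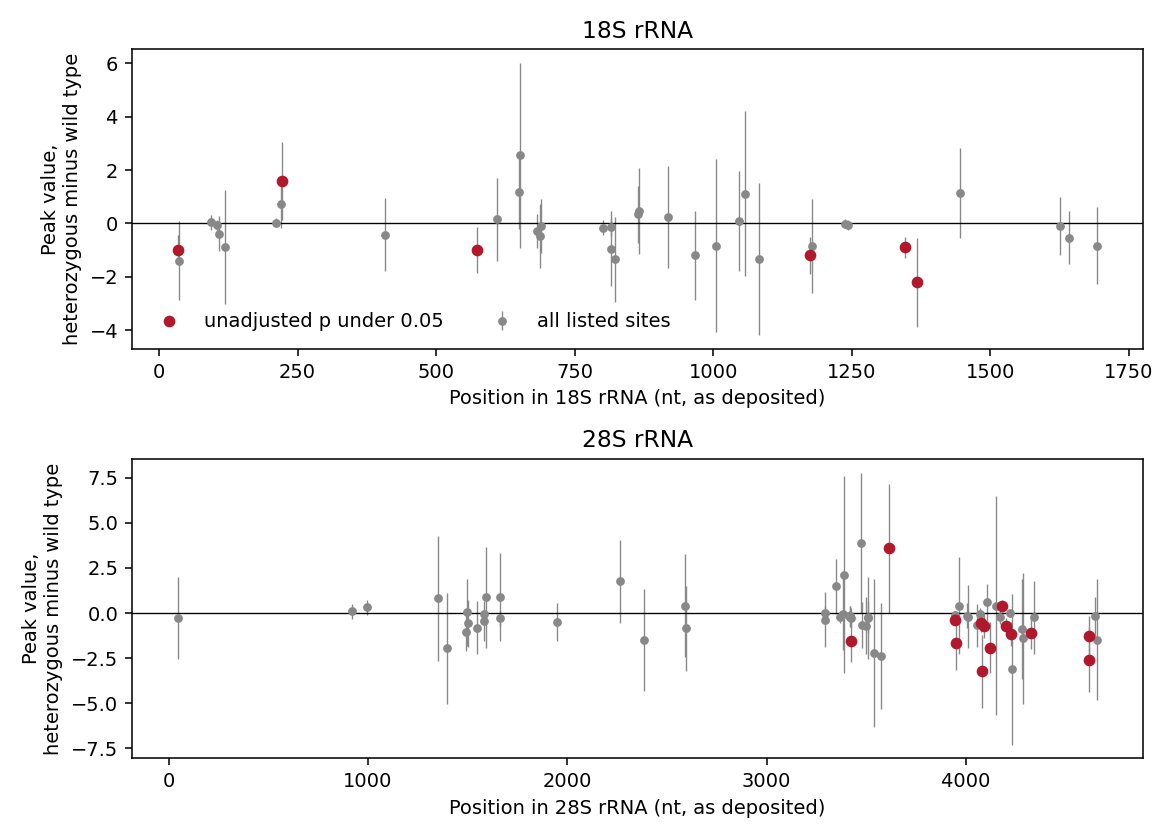
Difference in peak value, heterozygous minus wild type (vertical axis, authors' score), by position in 18S (top) and 28S (bottom), with 95% limma intervals over 7 animals. Red points mark the 20 sites with an unadjusted p under 0.05, of which 17 lie below 0, and none passed the adjusted threshold.

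The data bound the change in score at single sites, which is not a bound on the change in modification. Among the 82 sites with the authors' pass mark, the heterozygous mean was a median of 96.0% of wild type (interquartile range 85.6% to 102%, range 60.3% to 130%). The 95% limma interval excluded a 50% reduction of the score at 74 of the 82 sites and a reduction of 25% at 46. At the other sites such a reduction was not excluded with 7 animals. Each limit was divided by the wild-type mean as if that mean were known without error. The intervals hold for each site alone, not jointly over the 82.

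Grouped by level or by neighbourhood, most groups of sites had a lower heterozygous mean, and the design could hardly pass any after adjustment. Both level groups, or at least 7 of the 12 clusters, would need the smallest exact p. The 53 sites below the median level had a mean of 2.09 ± 0.195 (SD, n = 4) in wild type and 1.82 ± 0.106 (SD, n = 3) in heterozygotes, 87.3% of wild type, with lower heterozygous means at 42 sites (exact permutation p = 0.086, adjusted p = 0.171). Their difference of -0.27 was -0.18 without wild-type animal A. It was -0.47 when sites with a mean under 1 were removed first and -0.58 as a median over sites, each with an adjusted exact permutation p = 0.057. The 54 sites above it had 15.9 ± 0.464 and 15.6 ± 0.349, 97.7% of wild type, with lower heterozygous means at 33 sites (exact permutation p = 0.286, adjusted p = 0.286). Their difference of -0.36 was -0.18 without wild-type animal A, -0.22 without heterozygous animal F, and -0.56 without wild-type animal D or heterozygous animal E. Scaled by each animal's median it was -0.68 (adjusted exact permutation p = 0.429). As a median over sites it was -0.82 (adjusted exact permutation p = 0.286). Of 12 clusters of neighbouring sites, 9 had a lower and 3 a higher heterozygous mean. Among the higher, 28S positions 1581 to 1594 (0.13) turned to -0.025 on the log2 scale and to -0.28 without heterozygous animal E. The smallest p of the design was reached in 28S positions 1490 to 1500 (9.51 ± 0.183 and 8.99 ± 0.306) and 28S positions 3414 to 3426 (4.61 ± 0.161 and 4.14 ± 0.266), each with an exact permutation p = 0.0286 and an adjusted p = 0.171. The largest of the 12 differences in peak value, -1.25, was in 28S positions 4204 to 4231, with 5.46 ± 0.796 in wild type and 4.21 ± 0.493 in heterozygotes (exact permutation p = 0.086, adjusted p = 0.171).

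Site profiles of animals with the same genotype were not shown to be more alike than those of animals with different genotypes. Pearson's r across the 107 sites, which are not independent replicates, ranged from 0.956 to 0.993 over 21 pairs of animals. The mean was 0.981 within and 0.978 between genotypes, a difference of 0.0030 (one-sided exact permutation p = 0.257). With each animal left out it ranged from -0.0012, without heterozygous animal F, to 0.0066, without wild-type animal C.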

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

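The splits of the animals, the comparison with sites outside the pass mark and the removal of single animals were read as tests of the patterns below only after those patterns had been seen. At 6 of 107 sites, 1 of the 4 wild-type animals lay far from the other 3, and chance flags about 1 in 20 sites, or 5.35 here. Animal A stood apart at 28S position 4228 (2.29, others 1.33 to 1.39), 28S position 4341 (17.6, others 14.7 to 15.1) and 28S position 3418 (-0.68, others -1.15 to -1.11). Animal B stood apart at 28S position 3500 (6.07, others 4.03 to 4.22), animal C at 18S position 212 (-0.116, others -0.184 to -0.174) and animal D at 28S position 1594 (12.7, others 15.1 to 15.2).

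Among sites with the authors' pass mark, those of low peak value had a larger relative difference in the score, whose 0 is set by an unstated formula, so the ratios do not carry over to modification. The median log2 ratio of heterozygous to wild type was -0.19 (87.5% of wild type) at the 41 lower sites and -0.04 (97.6%) at the 41 higher ones, a gap of -0.16. Sites outside the pass mark differed by a median of -0.136 against -0.55 at the lower sites. A constant offset at every position would make these alike. The 95% bootstrap interval of -0.204 to -0.061 for the first median resampled positions, all measured in the same 7 animals. It holds no spread between animals, so a constant offset is not excluded. Of the 35 splits of the 7 animals, 1 gave as large a gap, the real one, and the largest other was 0.11, but the gap was picked from the same data, so this does not settle chance. Without wild-type animal A the gap was -0.042, and with any other animal left out it was between -0.108 and -0.161. Animal A may thus account for much of the gap, but other animals departed too. Against the mean of the 7 animals, the median log2 ratio in animal A was 0.166 at the lower sites and 0.055 at the higher ones. It was -0.196 and -0.037 in heterozygous animal F, and -0.102 and -0.044 in heterozygous animal G. In the other animals it was -0.019 to 0.051 and -0.033 to 0.010. Which animals make the gap was not tested, and an effect of genotype stays open, as untested.

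By limma, 20 sites reached an unadjusted p under 0.05, and 1 of the 35 splits, the real one, gave as many, while the highest other gave 19 with wild-type animals A, C and D set against the rest. None passed adjustment, and all 35 splits reach that count of 0, with a highest other of 0, which says nothing about chance. Without heterozygous animal F the count was 7, against 16 without E and 14 without G. Of the 15 splits of the 6 animals left, 5 gave as many, the real one included. The highest gave 23 sites, with wild-type animals A and D set apart. That split was picked after the counts were seen, and a structure among the animals other than genotype was not tested. Whether animal F is the source stays open: the count was the first criterion and the size of the differences replaced it after both were seen, and the median of 94.3% left without F (102% without E, 103% without G) decides nothing, because the sites were chosen with all 3 animals included. Genotype as the source is open too, since no other comparison separates it from differences between animals.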

How the results depend on the processing

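The restriction to sites with the authors' pass mark was chosen after the data were seen. No paired analysis was possible because 1 peak value is given for the 2 libraries of an animal, and the genotypes share no animal numbers. A replicate block was not run for the same reason. The count of sites past the adjusted threshold was 0 as reported and in all alternatives but 2. It was 1 when sites within 5 nt of another were removed and ranged from 0 to 1 when each animal was left out, with 1 without wild-type animal D. In each case the site was 18S position 1347, with differences of -0.89 and -1.01, and its adjusted p by limma ranged from 0.035 to 0.374 over the alternatives. Its unadjusted p was 0.00061 and 0.00033 in these fits against 0.0013 as reported, so fewer sites tested is not the whole cause, and the cause of the change was not tested. The mean over all sites passed only on the log2(value + 1) scale (-0.078). Taken as each animal's median over sites, the difference turned to 0.12 over all sites and 0.50 in 18S, neither past the exact test. That median can fall at a different site in each animal. The 18S minus 28S difference turned to -0.020 without sites within 5 nt of another, where the 18S difference was -0.41. Leaving out each animal gave a similarity difference of -0.0012 to 0.0066, negative without heterozygous animal F. The mean of the 28S cluster at 1581 to 1594 (0.13) turned to -0.025 on the log2 scale and ranged from -0.28 to 0.34 with each animal left out. Sites at 1 or more in every animal numbered 50 without close neighbours, 51 counted in wild type and 50 in heterozygotes, because fewer sites were counted. The unadjusted count of 20 was 13 with a minimum mean of 1, 12 with the pass mark only, 9 without close neighbours, 9 by the exact test per site and 7 without heterozygous animal F. Scaling by each animal's median moved the mean difference to -0.49 over all sites, -0.43 in 18S, -0.62 in 5.8S and -0.68 in the sites above the median level. Where the cause is not named, the cause was not tested. With all animals, direction and side of the threshold were the same for 37 other values of the main comparisons. With an animal left out, 48 values had the same direction. Some of the 37 could not turn, such as the 5.8S mean in settings that keep both its sites and their values. The directional fry test uses the reported difference again, and its mixed form is not among the 37. In 14 fits or tests the count of sites past the threshold stayed 0. A further 27 counts of sites with a peak value of at least 1 or 2, which have no test, stayed within 1.5 times. Many of these counts could not move, such as those in 1 genotype with an animal of the other left out. In the fit per site on the log2 scale, 8 sites below 0 in every animal have no value, and 99 were tested. The mean over all sites on that scale keeps all 107, with values below 0 set to 0. With any animal left out, the exact test has too few assignments to pass the threshold, so only its direction can be compared. Read depth is unknown.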

Other observations

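The test of neighbouring sites was chosen only after its result was seen. Some positions varied more within the wild-type group than between genotypes, and they are named here after their values were seen. At 28S position 4152 the wild-type animals A to D had peak values of 13.8, 23.6, 21.9 and 16.1, and the heterozygous animals E to G had 17.8, 21.5 and 18.4. At 28S position 3390 the wild-type values were 6.58, 15.7, 12.8 and 7.53, against 12.2, 12.7 and 13.5 in heterozygotes. At 18S position 652 they were 6.97, 12.04, 12.6 and 8.44, against 12.4, 13.0 and 12.3. In each of these sites animals A and D were below B and C, a difference whose source was not tested.

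Adjacent positions 4619 and 4620 of 28S had opposite signs in every animal. Position 4619 ranged from 8.05 to 12.5 and position 4620 from -11.1 to -8.63. At 28S position 3474, values ran from -6.91 in wild-type animal B to 1.66 in heterozygous animal G.

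It was asked whether neighbouring sites along 18S and 28S shift together, as shared local signal would make them. The correlation of the moderated statistic between neighbours was 0.036 (one-sided permutation p = 0.285 over shuffled orders within each rRNA), so no such relation was found across sites. Listed positions next to each other can lie far apart, such as 28S positions 45 and 920. Shared signal between close sites alone is therefore not excluded.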
